A study of Mus musculus with 8 samples.

How the data were processed

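Total RNA of islets of Langerhans from the AKR/J and C57Bl/6J strains, both given a high-fat diet, was profiled on Affymetrix mouse expression arrays, 8 arrays in all, with 5 µg of RNA per array per the labels. Samples were grouped by the strain in their titles, 4 per strain, and each sample combined islets from 2 mice, so p-values measure the spread between pools. The titles number the samples without any number shared between the strains.

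The value table of the series holds intensity values on a linear scale that the authors made with GCRMA, per the submitters' processing notes, a method that corrects background by probe sequence, normalizes across arrays and summarises probes to probe sets; its version is not given in the sources used here. Array quantiles agreed within 0.0904 on the log2 scale, so no further normalization was applied, and values were log2-transformed. Values ran from 1.54 to 69278. The deposited per-array files hold a MAS5-type intensity signal, scaled to the same trimmed mean on each array, and a detection p-value for each probe set; per the file headers these are a signal, a detection call and its p-value. A detected call was given exactly where that p was under 0.05. Columns of the value table were matched to the per-array files by their deviations from the probe set means, with r of at least 0.742 for matching pairs and at most 0.516 for others. GCRMA borrows strength across arrays and compresses the brightest signals, and a sequence difference between strains under a probe changes its signal without a change in transcript level. The files give no scan date, so a batch could not be fitted.

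Of 45101 probe sets, 64 controls were left out. GEO's platform annotation names 1 gene symbol for 34945 of the rest, several for 932 and none for 9160; probe sets with several or none were tested but not named. Entrez identifiers matched 34754 probe sets to a RefSeq gene table (GRCm38.p6), which changed 0 symbols. No genome build is named in the files, so no coordinates are given and the table served only for names and for which genes are neighbours. Of 496 entries of the gene lists, 440 had a probe set that names them alone and 56 are not reported here.

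The fit kept the 20772 probe sets detected on at least 4 of 8 arrays, 18491 of them with 1 symbol. AKR/J minus C57Bl/6J differences were fitted with limma's lmFit and eBayes and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Each of the 10891 genes was represented by its brightest probe set over all arrays. Where a probe set was not detected on any array of the dimmer strain, the fold is a bound: the brighter strain's mean against the dimmer strain's mean of, per array, the higher of its own value and the lowest value among detected probe sets. These lowest values were only 0.618 to 0.856 on the log2 scale, so each bound printed here equals the plain fold. Of 21 gene lists (pathways and cell types that an islet preparation can hold), the shift was tested with limma's camera, two-sided, with a preset correlation of 0.01 and again with an estimated one, and the p-values were adjusted over the lists. RNA quality measures were compared by exact permutation over the 70 assignments of arrays to strains.

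The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 8 genes with the largest difference in each direction whose strains do not overlap; the islet hormones and Nnt; up to 4 called members of each list, smallest p first, or the 2 brightest where none was called; and the measured strain-allele genes. Alternatives were no filter or detection on all 8 arrays, the MAS5-type signals with a floor at the 5th percentile and quantile normalization, a further quantile normalization, centring on array medians, eBayes with trend and robust, array weights, probe sets without the _x_at and _s_at suffixes, the acinar list's mean as a covariate, the mean of all probe sets of a gene, camera with an estimated correlation and each array left out.

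On simulated data with the residual spread of these arrays and 200 changed probe sets among 20772, the fit recovered 43.3% of those changed 1.5-fold, 77.6% of those changed 2-fold and 95.5% of those changed 4-fold, with 10 false calls, 6.49% of the calls. A simulated list of 25 genes shifted by 0.8 on the log2 scale was found and 0 of 20 unshifted lists were called. Genes were drawn independently in this simulation, whereas the estimated correlation within the real lists ran up to 0.407. It therefore does not show how often camera with the preset correlation calls unshifted lists of correlated genes. R 4.3.3 with limma 3.58.1 was used, and Python 3.11.15 with matplotlib 3.10.9 for figures.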

Results

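Gene expression was measured in pancreatic islets of AKR/J and C57Bl/6J mice, a pair of inbred strains, after 3 months on a high-fat diet. Islets are the clusters of hormone-secreting cells in the pancreas, in which beta cells make insulin, alpha cells glucagon, delta cells somatostatin and PP cells pancreatic polypeptide. There were 4 RNA samples per strain, each pooled from 2 mice and hybridised to its own Affymetrix mouse expression array, numbered 1 to 4 for AKR/J and 5 to 8 for C57Bl/6J. No group on another diet was analysed here, so every comparison is between strains on the same diet. Between 43.7% and 48.1% of the probe sets that were not array controls were detected per array. Over the tested probe sets, arrays of one strain correlated at r = 0.988 to 0.993 in AKR/J and 0.985 to 0.992 in C57Bl/6J, against 0.966 to 0.975 between strains. The number of arrays limits the precision of every value. RNA quality signs were not identical in the strains. The share of detected probe sets was 44.9% ± 1.55 (SD, n = 4) in AKR/J and 47.0% ± 1.18 (SD, n = 4) in C57Bl/6J (two-sided exact permutation p = 0.114, adjusted 0.114). The log2 ratio of the 3' to the 5' control probe set was 0.79 ± 0.06 against 0.71 ± 0.03 for actin (exact p = 0.114, adjusted 0.114). For Gapdh it was -0.39 ± 0.03 against -0.23 ± 0.11 (exact p = 0.0286, the smallest that 4 against 4 arrays allow; adjusted 0.0858 over 3 measures).

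The comparison of the strains asked which islet genes were expressed at different levels in the AKR/J and C57Bl/6J strains on this diet. Of 10891 genes tested, 958 were higher in AKR/J and 1033 were higher in C57Bl/6J, and 467 of these 1991 differed at least 2-fold, 190 higher in AKR/J and 277 higher in C57Bl/6J. The gene with the largest excess in AKR/J was Rab3c, a small GTPase of secretory vesicles, at a log2 value of 10.23 ± 0.28 in AKR/J and 5.12 ± 0.30 in C57Bl/6J (SD, n = 4 each; 34.6-fold; limma adjusted p = 1.32e-06). The largest excess in C57Bl/6J was that of H2-Q2, a class I gene of the major histocompatibility complex (MHC), which was not detected on any AKR/J array and was at least 76.0-fold higher in C57Bl/6J (adjusted p = 1.88e-07). After Rab3c, the genes furthest above C57Bl/6J in AKR/J were Serpina1b, of the alpha-1-antitrypsin family (at least 24.5-fold), Pianp (21.2-fold), Tmem87a (at least 18.1-fold), the digestive protease gene Ctrc (16.3-fold), the retinaldehyde dehydrogenase gene Aldh1a3 (14.6-fold), the apolipoprotein gene Apof (12.9-fold) and 6330403K07Rik (12.5-fold). After H2-Q2, those furthest above AKR/J in C57Bl/6J were Rpgrip1 (at least 47.8-fold), the class I genes H2-K1 (39.3-fold) and H2-D1 (22.2-fold), the immunoglobulin A heavy chain gene Igha (14.7-fold), the Golgi GTPase gene Rab6b (13.8-fold; log2 difference -2.43 with the mean of its 3 probe sets, against -3.78), the kallikrein gene Klk1b5 (12.98-fold) and Tmed11 (12.4-fold). Adjusted p for these 16 genes ran from 4.14e-08 for Rpgrip1 to 0.00133 for Igha. A bound is given where the probe set was not detected on any array of the dimmer strain; Apof and Igha were each detected on 1 of its 4 arrays and Pianp on 2, so the sizes of these 3 rest on signals near background. Close paralogs exist for Serpina1b, Klk1b5 and the class I genes, and their probe sets can take signal from these. Only 1 probe set each was tested for Pianp, Tmem87a, Ctrc, Apof, 6330403K07Rik, H2-Q2, Rpgrip1 and Tmed11. For these genes a sequence difference between strains under the probes could not be told from a difference in transcript level.

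At the level of probe sets, 2968 of 20772 passed the adjusted threshold, 1369 higher in AKR/J and 1599 higher in C57Bl/6J, and 813 of them differed at least 2-fold. The 4 arrays of one strain all lay above the 4 of the other for 2737 genes, which is 25.1% of those tested, where chance gives 2.86%. Probe sets of one gene did not always go the same way. For Rab3c, 3 of 3 tested probe sets were higher in AKR/J, by 5.11 to 5.85 on the log2 scale. For H2-D1, 3 of 4 were higher in C57Bl/6J, by 22.2-fold to at least 76.0-fold, while 1 was 320-fold higher in AKR/J (log2 difference 8.32; adjusted p = 1.44e-09). For H2-K1, 3 of 3 were higher in C57Bl/6J, by 39.3-fold, 51.5-fold and 2.29-fold, the last with a similar mean brightness to the first. Without C57Bl/6J array 8 that probe set was the brightest and the H2-K1 log2 difference was -1.28 in place of -5.29. For the peroxiredoxin gene Prdx2, the brighter probe set was 1.35-fold higher in AKR/J and the dimmer one 13.1-fold higher in C57Bl/6J, so that the mean of its probe sets gave a log2 difference of -1.64 in place of 0.43. With arrays 1, 2, 5 and 6 alone 904 genes passed, and with arrays 3, 4, 7 and 8 alone 403 genes passed, each with 2 arrays per strain.

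**Figure D1:**
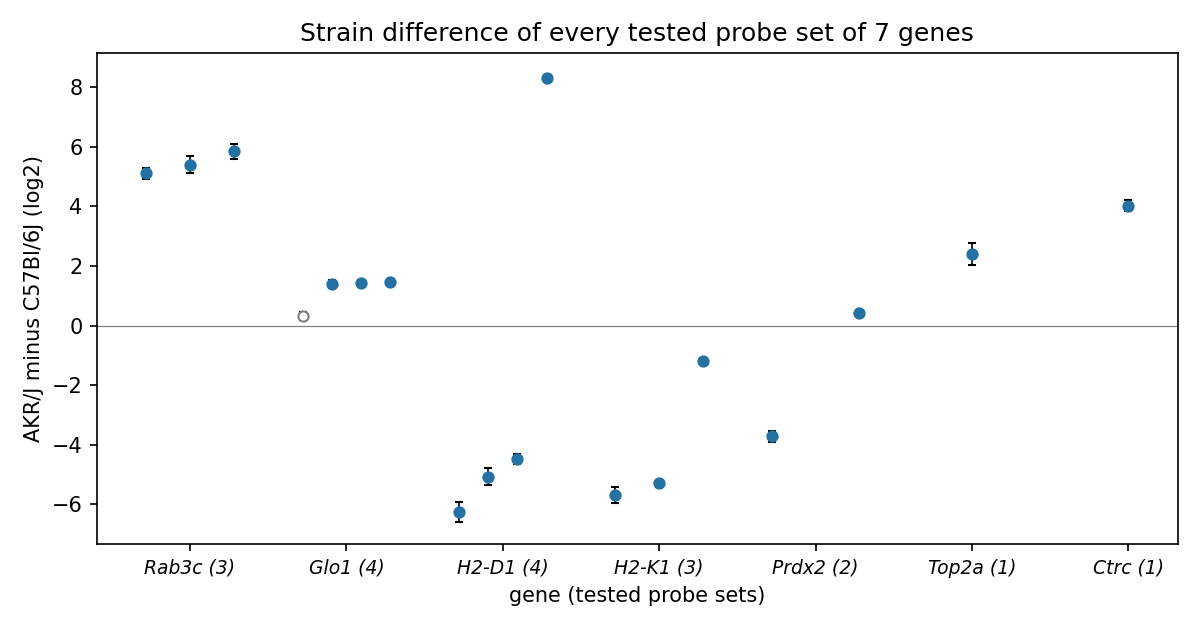
Log2 difference between AKR/J and C57Bl/6J (vertical axis; above 0 is higher in AKR/J) for every tested probe set of 7 genes (horizontal axis, number of tested probe sets in brackets), over 4 arrays per strain. Bars are the standard error of the limma fit, filled points passed an adjusted p of 0.05, and the 4 probe sets of H2-D1 run from -6.25 to 8.32 while the 3 of Rab3c all lie above 5.

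Among the islet hormones, pancreatic polypeptide passed the threshold and the others did not, though which of them passed depended on the processing. Ppy was at 14.67 ± 0.19 in AKR/J and 13.77 ± 0.47 in C57Bl/6J on the log2 scale (SD, n = 4 each), a 1.86-fold excess in AKR/J (limma adjusted p = 0.0252). Ins2, an insulin gene, was at 15.71 ± 0.07 and 15.50 ± 0.05 (adjusted p = 0.0681), and Iapp, the amylin gene co-secreted with insulin, at 15.63 ± 0.07 and 15.45 ± 0.03 (adjusted p = 0.0942). For glucagon (Gcg) and somatostatin (Sst) the log2 differences were 0.01 (adjusted p = 0.954) and 0.06 (adjusted p = 0.665). The call of Ppy was lost without AKR/J array 1 (adjusted p = 0.0636), 2 (0.064) or 3 (0.0577) and without C57Bl/6J array 8 (0.0627). With no filter on dim probe sets Ins2 (0.0326) and Iapp (0.0295) passed and Ppy did not (0.0675). Ins2 also passed after a further quantile normalization (0.00788), and Ins2 (0.0156) and Iapp (0.0215) did with trend and robust variance. Ins2, Iapp and Gcg lay near the top of the array's range, where differences can be compressed.

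Beta cell genes moved in both directions. Of 32 measured members of the beta cell list, 3 were higher in AKR/J, 5 were higher in C57Bl/6J and 24 did not pass; adjusted over the list alone, 4 and 9 passed. The granin genes of secretory granules Chgb (1.83-fold), Scg2 (1.29-fold) and Scg3 (1.27-fold) were higher in AKR/J. The granin gene Chga went the other way, 1.21-fold higher in C57Bl/6J (limma adjusted p = 0.0389). Ucn3, a peptide of mature beta cells, was 1.43-fold higher in C57Bl/6J. With the MAS5-type signals Ucn3 and Scg3 did not pass (adjusted p = 0.344 and 0.346). As a set the list did not shift (median log2 difference 0.01, mean -0.03, camera adjusted p = 0.889). Of 10 other endocrine genes, 2 were higher in AKR/J, which were Ppy and the transthyretin gene Ttr (1.20-fold, adjusted p = 0.0312), and 1 was higher in C57Bl/6J, the amino acid transporter gene Slc38a5 (1.55-fold, adjusted p = 0.0346); adjusted over the list alone the counts were the same, and the set did not shift (median 0.06, adjusted p = 0.657). Ttr lost its call without array 1, 2, 4, 5, 6 or 7 (adjusted p up to 0.0792) and Slc38a5 without array 2, 3, 4, 5, 6 or 7 (up to 0.0917), and neither passed with the MAS5-type signals (0.117 and 0.112). Of 17 measured genes that normal beta cells keep low, 1 was higher in AKR/J, the antibody receptor gene Fcgrt (1.29-fold), and 3 were higher in C57Bl/6J, namely Pdgfra (2.48-fold), the glutathione transferase gene Mgst1 (1.97-fold) and Maf (1.35-fold); adjusted over the list alone, 3 and 7 passed. This set did not shift by camera either (median -0.10, camera adjusted p = 0.48). By exact permutation of its mean per array it had the smallest possible p (0.0286, adjusted 0.0751). Maf was not called without array 1, 2, 4, 5, 6 or 8 (adjusted p up to 0.105), nor Fcgrt and Mgst1 with the MAS5-type signals (adjusted p = 0.0936 and 0.0682).

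Across the 21 gene lists, 8 shifted by camera with its preset correlation of 0.01, and none of the 8 held with an estimated correlation. An exact permutation test of each list's mean value per array was chosen after the data were seen. It gave its smallest possible p of 0.0286 for 8 lists, with an adjusted p of 0.0751, so 0 lists passed. No list could pass unless most of the 21 reached that smallest p, so failing it does not count against a list there. These 8 lists include the genes that normal beta cells keep low, which camera did not call. They leave out oxidative phosphorylation (exact permutation p = 0.0571, adjusted 0.0999). In 7 of the 35 ways to split the arrays into 4 and 4, the real one included, at least 8 lists passed by camera. Apart from the real one, these splits kept most arrays of each strain together, so they held part of the strain contrast.

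**Figure D2:**
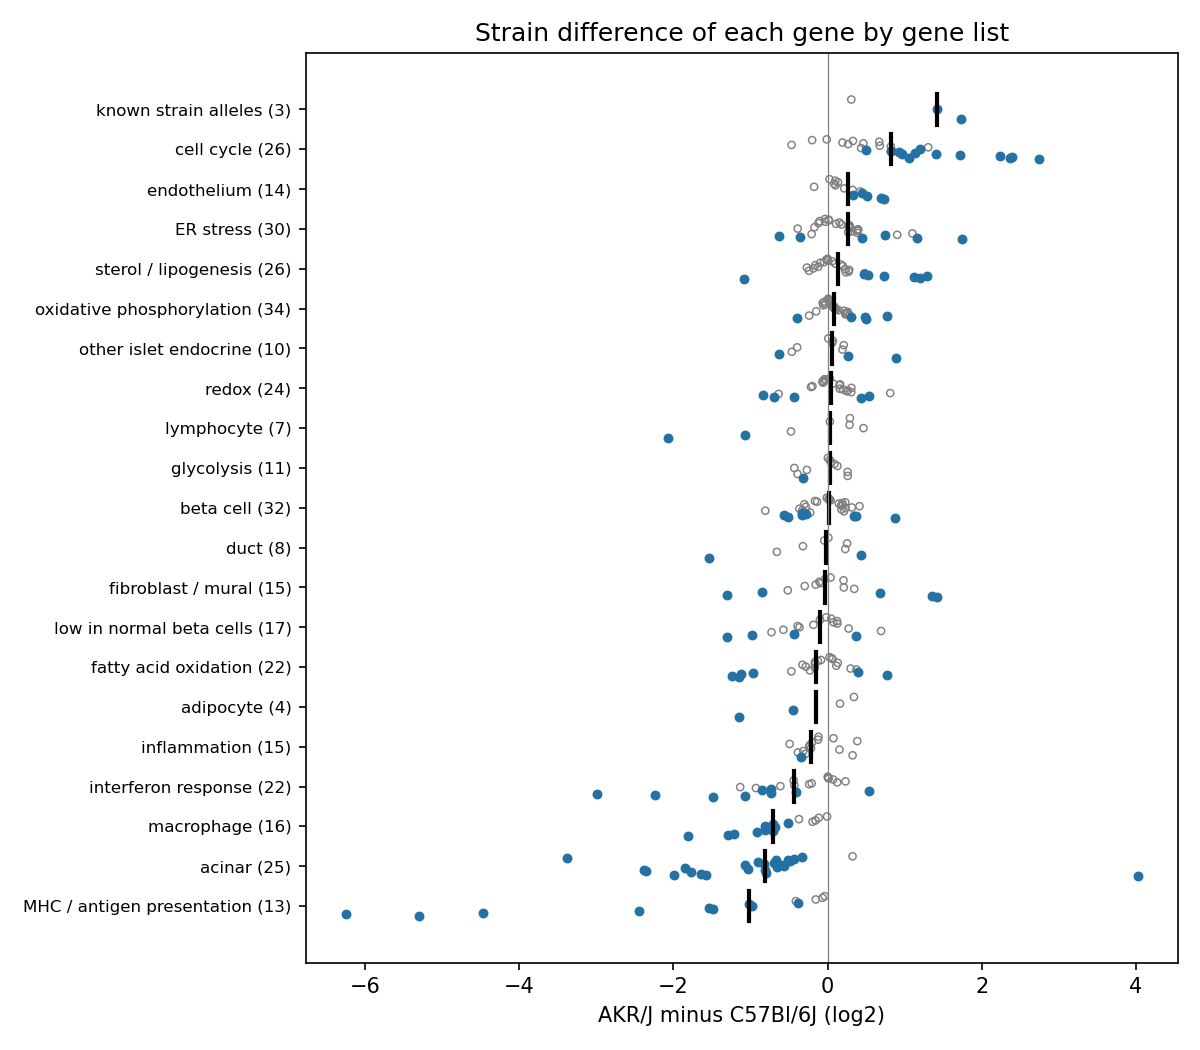
Log2 difference between AKR/J and C57Bl/6J (horizontal axis; above 0 is higher in AKR/J) of each measured gene in 21 gene lists (vertical axis, number of measured genes in brackets), over 4 arrays per strain. Filled points passed an adjusted p of 0.05 and black bars mark list medians, which run from -1.02 for antigen presentation to 1.42 for the strain alleles.

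Genes of acinar cells, the digestive-enzyme cells that surround the islets, were lower in AKR/J almost throughout. Of 25 measured members, 23 were lower, 1 was higher and 1 did not pass, with the same counts adjusted over the list alone. The lipase-related gene Pnliprp2 was 2.97-fold lower in AKR/J, the trypsin inhibitor gene Spink1 3.98-fold and the zymogen granule gene Cuzd1 3.11-fold (adjusted p = 3.83e-05 for the latter pair), whereas Ctrc, which encodes chymotrypsin C, was 16.3-fold higher in AKR/J. The list's median log2 difference was -0.81 (camera adjusted p = 3.44e-16; adjusted p = 0.15 with an estimated correlation), and -0.51 with the MAS5-type signals. The mean over the list, relative to the mean of all 8 arrays, was -0.46 ± 0.10 in AKR/J and 0.46 ± 0.07 in C57Bl/6J (SD, n = 4 each). Because this value and strain correlated at r = -0.987 across the arrays, fitting it as a covariate left 4 genes past the threshold, and strain and acinar content cannot be separated in that fit.

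Most measured macrophage genes were also lower in AKR/J. Of 16, 11 were lower, 0 were higher and 5 did not pass, with the same counts adjusted over the list alone. The complement genes C1qc (3.50-fold) and C1qb (2.33-fold), the lysosomal protease gene Ctss (2.46-fold) and the growth factor receptor gene Csf1r (1.89-fold) were among them. The related complement gene C1qa, brighter than C1qb and C1qc, did not pass (log2 values 9.15 in AKR/J and 9.16 in C57Bl/6J, limma adjusted p = 0.974). With the MAS5-type signals C1qc (log2 difference -1.10 against -1.81) and Ctss (-0.75 against -1.30) differed less. The median was -0.71 (camera adjusted p = 1.3e-06; adjusted p = 0.291 with an estimated correlation). Of 7 lymphocyte genes, 0 were higher in AKR/J and 2 were lower, Jchain of the immunoglobulin joining chain (4.21-fold, adjusted p = 0.0394) and Cd52 (2.10-fold, adjusted p = 0.0411). Adjusted over the list alone the counts were the same. Jchain lost its call without array 2, 3, 4, 6, 7 or 8 (adjusted p up to 0.0997) and Cd52 without array 1, 2, 3, 6, 7 or 8 (up to 0.0961). The lymphocyte median was 0.03 and the mean -0.36, and the list did not shift (adjusted p = 0.637). Of 8 duct genes, the tetraspanin gene Tspan8 was 2.90-fold lower in AKR/J (log2 difference -1.01 with the mean of its probe sets against -1.54) and the clusterin gene Clu 1.36-fold higher, the latter not called without array 1, 2, 3, 4 or 8 (adjusted p up to 0.0792); adjusted over the list alone, 2 were higher and 3 lower, and the list did not shift (median -0.02, adjusted p = 0.768). Of 4 fat cell genes, the lipase gene Lpl was 2.21-fold lower in AKR/J and the fatty acid carrier gene Fabp4 1.37-fold lower, with the same counts over the list alone and no shift of the list (median -0.15, adjusted p = 0.589). Fabp4 was not called without array 1, 2, 6 or 7 (adjusted p up to 0.0645).

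Most measured genes of antigen presentation were lower in AKR/J, the strain with the k haplotype of the MHC, than in C57Bl/6J, which has the b haplotype. Of 13 measured, 9 were lower, 0 were higher and 4 did not pass; adjusted over the list alone, 10 were lower. H2-K1 was at 6.72 ± 0.25 in AKR/J and 12.02 ± 0.04 in C57Bl/6J (SD, n = 4 each; adjusted p = 1.23e-07) by its brightest probe set and at 8.48 ± 0.11 and 9.67 ± 0.17 by another, and the class II gene H2-Ab1 was 5.42-fold lower in AKR/J (adjusted p = 0.000112; detected on 1 of 4 AKR/J arrays), 2.85-fold by another of its probe sets and by 1.29 on the log2 scale, against 2.44, with the MAS5-type signals. The median was -1.02 (camera adjusted p = 1.4e-09; adjusted p = 0.15 with an estimated correlation), and -0.40 over 18 members with no filter on dim probe sets. The size of the H2-K1 difference and the direction of the H2-D1 difference depended on the probe set. For H2-D1, 1 probe set was at 11.67 in AKR/J and 3.34 in C57Bl/6J, and another at 5.68 and 11.92. For these class I genes a sequence difference under the probes could not be told from a difference in transcript level. The counts and the median of this list take 1 probe set per gene and hold the same limit. Of 22 interferon-response genes, 8 were lower in AKR/J, 1 was higher and 13 did not pass; adjusted over the list alone, 9 were lower and 1 was higher. The antiviral gene Rsad2 was 7.98-fold lower, Oasl2 4.70-fold, the GTPase gene Igtp 2.81-fold and the RNA sensor gene Ifih1 2.09-fold. With the MAS5-type signals Igtp (log2 difference -0.77 against -1.49) and Oasl2 (-1.49 against -2.23) differed less. The interferon median was -0.44 (camera adjusted p = 0.000861; adjusted p = 0.32 with an estimated correlation, and 0.738 with the acinar covariate). Macrophage genes, with a median of -0.71, were lower on the same arrays. Of 15 inflammation genes, 1 passed, the tumour necrosis factor receptor gene Tnfrsf1a (1.27-fold lower in AKR/J, adjusted p = 0.0205), which lost its call without array 2, 4 or 5 (adjusted p up to 0.0546) and with the MAS5-type signals (adjusted p = 0.335); the count over the list alone was also 1, and the list did not shift (median -0.22, adjusted p = 0.485).

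**Figure D3:**
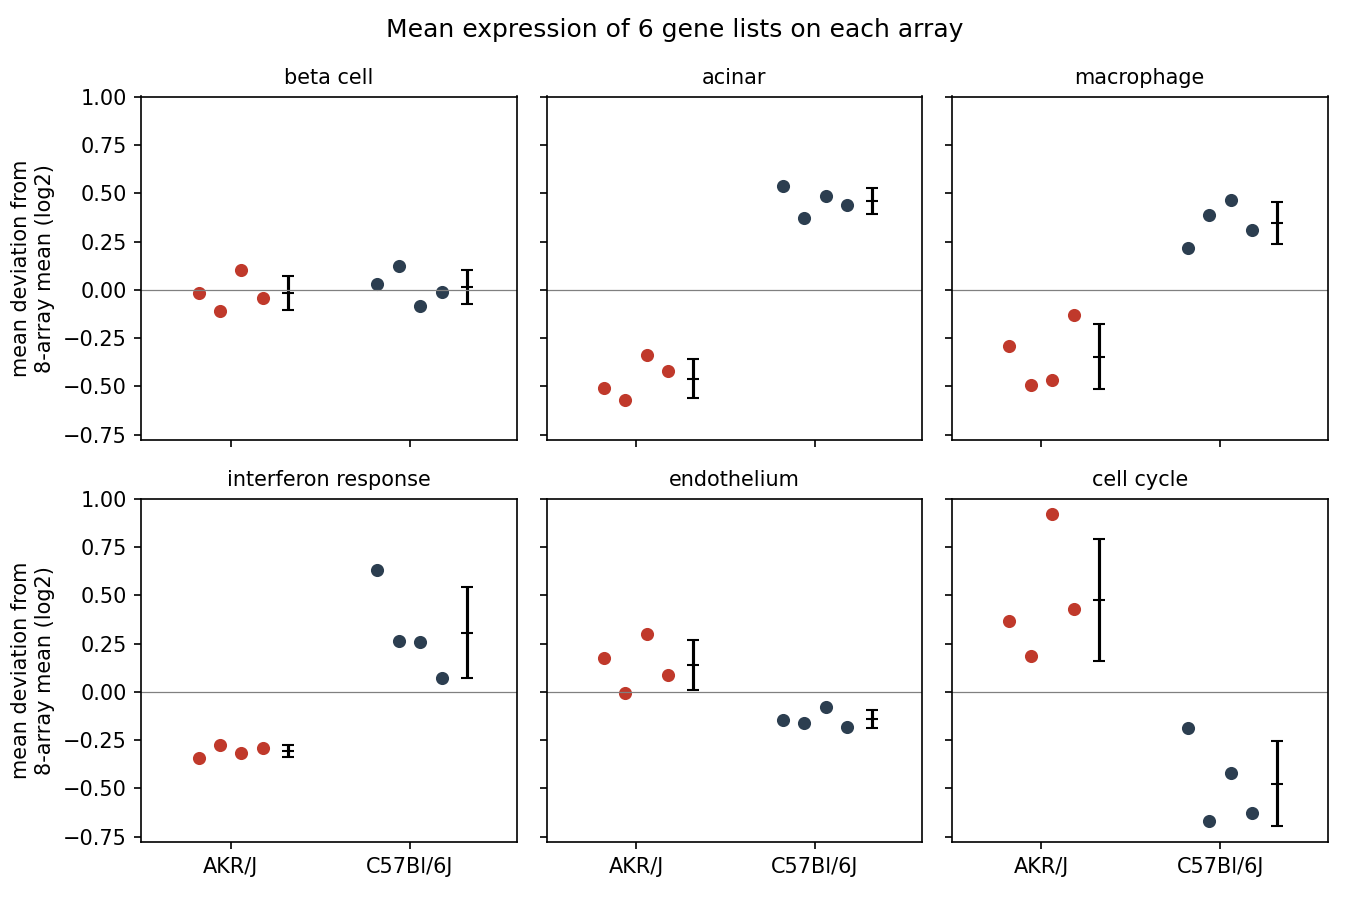
Mean log2 deviation of 6 gene lists from the mean of all 8 arrays (vertical axis), for each of the 4 arrays per strain (points; horizontal axis), with bars for the mean and SD of each strain. The AKR/J and C57Bl/6J arrays do not overlap for the acinar, macrophage, interferon, endothelial and cell cycle lists, and they overlap for the beta cell list, whose means are -0.02 and 0.02.

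Cell cycle genes, which are expressed in dividing cells, were all higher in AKR/J where they passed. Of 26 measured, 14 were higher, 0 were lower and 12 did not pass; adjusted over the list alone, 18 were higher. Cks2, a partner of the mitotic kinase, was at 7.56 ± 0.25 in AKR/J and 4.81 ± 0.70 in C57Bl/6J (SD, n = 4 each; 6.70-fold; adjusted p = 0.000687). The mitotic kinase gene Cdk1 (5.16-fold), the topoisomerase gene Top2a (5.27-fold) and the ribonucleotide reductase gene Rrm1 (2.08-fold; log2 difference 0.55 with the MAS5-type signals against 1.06) were also higher. The median was 0.82 (camera adjusted p = 1.62e-07; adjusted p = 0.33 with an estimated correlation). Several of these transcripts were dim in C57Bl/6J, where Cdk1 was detected on 2 of 4 arrays and Cks2 on 3 of 4.

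Some endothelial markers were higher in AKR/J on the same arrays. Of 14 measured, 5 were higher, 0 were lower and 9 did not pass; adjusted over the list alone, 6 were higher. These included Ramp2 (1.66-fold), the junction gene Cdh5 (1.62-fold), the receptor gene Tek (1.43-fold) and Esam (1.25-fold), with a list median of 0.27 (camera adjusted p = 0.00363; adjusted p = 0.37 with an estimated correlation). Tek and Esam were not called with the MAS5-type signals (adjusted p = 0.132 and 0.161). Markers of fibroblasts and mural cells, the contractile cells around capillaries, divided. Of 15, 3 were higher in AKR/J, the pericyte gene Rgs5 (2.67-fold, adjusted p = 1.72e-05) and the matrix genes Postn (2.55-fold) and Sparc (log2 difference 0.68), and 2 were lower, among them the fibroblast receptor gene Pdgfra (2.48-fold). The counts over the list alone were the same, and the list did not shift (median -0.03, mean 0.06, adjusted p = 0.638).

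In oxidative phosphorylation, by which mitochondria make ATP, 4 of 34 genes were higher in AKR/J, including Cox6a1 (1.41-fold; log2 difference 0.28 with the mean of its probe sets against 0.50), Ndufa1 (1.39-fold) and Uqcrfs1 (1.23-fold; adjusted p = 0.108 with the MAS5-type signals), and 1 was lower, the succinate dehydrogenase gene Sdha (1.32-fold), with the same counts over the list alone. Its median of 0.08 passed by camera (adjusted p = 0.0402; adjusted p = 0.758 with an estimated correlation) but not without AKR/J array 2 (0.159) or 3 (0.0621) or C57Bl/6J array 8 (0.14). It was also lost with no filter (0.105), the MAS5-type signals (0.154), a further quantile normalization (0.108), array weights (0.0575), probe sets without the _x_at and _s_at suffixes (0.133), the mean of a gene's probe sets (0.0652) and arrays 3, 4, 7 and 8 alone (0.152). In the endoplasmic reticulum stress list, 4 of 30 were higher in AKR/J, among them the protein-folding and degradation genes Derl3 (3.34-fold), Pdia4 (2.24-fold) and Manf (1.36-fold), and 2 were lower, among them Sel1l (1.28-fold). With the MAS5-type signals Manf (adjusted p = 0.115) and Sel1l (0.0558) did not pass, and Sel1l lost its call without array 1, 4, 5 or 6 (adjusted p up to 0.0572). The counts over the list alone were the same, and the list missed the threshold (median 0.27, adjusted p = 0.0524; adjusted p = 0.758 with an estimated correlation of 0.407). It passed without AKR/J array 3 (0.0135) or 4 (0.015) and without C57Bl/6J array 5 (0.00163) or 6 (0.0455). It also passed with detection on all 8 arrays (0.0395), centring (0.0453), probe sets without the _x_at and _s_at suffixes (0.0499) and the mean of a gene's probe sets (0.0491). With arrays 1, 2, 5, 6 and 3, 4, 7, 8 fitted as a block it passed at 0.0112, and in each set alone at 0.0162 and 0.00566. Within strains the endoplasmic reticulum stress median was lower in arrays 3, 4, 7 and 8 than in the others, by 0.26 in AKR/J and 0.28 in C57Bl/6J.

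Of 26 sterol and lipid synthesis genes, 6 were higher in AKR/J, among them the desaturase genes Scd1 (2.30-fold; log2 difference 0.67 with the mean of its probe sets against 1.20), Scd2 (2.18-fold) and Fads2 (2.44-fold; 0.76 with the MAS5-type signals against 1.28), and 1 was lower, the sterol desaturase gene Sc5d (2.12-fold by its brightest probe set), with the same counts over the list alone. The 2 other Sc5d probe sets did not pass (log2 differences -0.01 and 0.31), and the mean of all 3 gave -0.26 (adjusted p = 0.0541). The list did not shift (median 0.14, camera adjusted p = 0.0953, and 0.758 with an estimated correlation). It did pass without AKR/J array 2 (0.0231) or C57Bl/6J array 6 (0.0455) and with arrays 3, 4, 7 and 8 alone (0.00114). With the acinar covariate, which cannot be separated from strain, it also passed (median 0.76, camera adjusted p = 0.0192). Of 22 fatty acid oxidation genes, 4 were lower in AKR/J, among them the dehydrogenase gene Acadl (2.21-fold), the fatty acid transporter gene Cd36 (2.36-fold; log2 difference -0.76 with the mean of its probe sets against -1.24) and the kinase gene Pdk4 (2.18-fold), and 2 were higher, among them Eci1 (1.70-fold); adjusted over the list alone, 5 were lower and 2 higher, and the list did not shift (median -0.14, adjusted p = 0.326). Of 24 redox genes, 2 were higher in AKR/J, the glutathione peroxidase gene Gpx3 (1.46-fold) and Prdx2 by its brighter probe set (1.35-fold), and 3 were lower, among them Gstm1 (1.61-fold) and the glutathione reductase gene Gsr (1.35-fold); over the list alone, 2 were higher and 4 lower, and the list did not shift (median 0.05, adjusted p = 0.638). Gstm1 did not pass with the MAS5-type signals (adjusted p = 0.347), nor Gsr with the mean of its probe sets (0.0634), of which the other was at a log2 difference of 0.04. Gpx3 was not called without AKR/J array 4 (adjusted p = 0.057) or C57Bl/6J array 8 (0.052). Of 11 glycolysis genes, Pfkp alone passed (1.24-fold lower in AKR/J, adjusted p = 0.0452), none did over the list alone, and Pfkp was not called without any single array other than 3 (adjusted p up to 0.0958). The glycolysis median was 0.03 and its mean -0.05 (adjusted p = 0.909).

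Of 3 measured genes listed for known allele differences among inbred strains, 2 were higher in AKR/J, and 3 were over the list alone. Ifi202b, an interferon-inducible gene, was at least 3.33-fold higher in AKR/J and not detected in C57Bl/6J (log2 difference 1.73, and 3.81 with the MAS5-type signals), and Glo1, a glyoxalase gene whose copy number varies among strains, was 2.67-fold higher, at 10.74 ± 0.25 against 9.32 ± 0.05 (SD, n = 4 each; adjusted p = 0.000135). Of the 4 Glo1 probe sets, 3 passed and were higher in AKR/J. The median of the list was 1.42 (camera adjusted p = 0.00105; adjusted p = 0.15 with an estimated correlation), 0.31 over 5 members with no filter and 0.24 with the acinar covariate, where the call was lost (adjusted p = 0.348). Nnt, the transhydrogenase gene in which C57Bl/6J is known to carry a deletion, was at 10.54 ± 0.17 in AKR/J and 10.23 ± 0.19 in C57Bl/6J (adjusted p = 0.111). Its other probe set was at 9.39 ± 0.33 and 9.73 ± 0.33, the other way (log2 difference -0.34, adjusted p = 0.321). Where its probes lie relative to the deletion was not known here, so Nnt checks no label.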

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

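The tests of array yield, of agreement between probe sets of the 4-fold group, and of cell cycle genes against endothelial markers, against the split of the arrays and against other splits were chosen after the values were seen; the sets of arrays 1, 2, 5, 6 and 3, 4, 7, 8 were themselves found in the data, as was the division into heat shock and early response genes.

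A single array lay far from the other 3 of its strain in 13 of 212 groups of 4 examined, where chance flags about 1 in 20. On log2 values, C57Bl/6J array 5 stood apart for Tmem87a (2.60), H2-D1 (11.48), Iapp (15.40) and Cdk1 (4.78), array 7 for Scg2 (15.05) and Maf (5.12), and array 8 for Acadl (9.29). In AKR/J, array 3 stood apart for Apof (7.74), Ttr (15.08) and Tspan8 (6.65), array 1 for Sparc (10.37) and array 4 for Mgst1 (7.58). The mean deviation of the antigen presentation list was -1.19 on AKR/J array 2, against -0.88 on the nearest array.

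The arrays divided within both strains along the same genes. The difference of arrays 3 and 4 from 1 and 2 in AKR/J correlated at r = 0.355 across genes with that of arrays 7 and 8 from 5 and 6 in C57Bl/6J, where the 8 other pairings gave -0.11 to 0.16; genes are not independent replicates. An effect of array yield, measured by the detected share alone, is argued against. That share differed by 2.36 percentage points in AKR/J and by -1.99 in C57Bl/6J. Each value sets 2 arrays against 2, and other quality measures were not compared between the sets, so array quality in general is not ruled out. Time of day at collection may contribute: 9 of 9 clock genes not seen before, among them Arntl (log2 difference of arrays 3, 4, 7, 8 from the others -1.22) and Tef (0.95), lay on the side their phase predicts (one-sided exact binomial p = 0.00195), although these genes are co-regulated and none passed alone. Stress during handling stays open, with 21 of 27 genes lower in arrays 3, 4, 7 and 8 (77.8%, one-sided exact binomial p = 0.00296), which are 14 of 14 heat shock genes and 7 of 13 early response genes. Of the heat shock genes 6 passed alone, among them Stip1 (adjusted p = 0.0228) and Hspa8 (0.0254), though the sets of arrays were defined from the same values. Collection days and hours are not in the labels, and each set holds both strains, so the split is not the strain difference.

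Among the 204 probe sets that differed at least 4-fold, a strain difference in transcript level and a sequence difference under the probes compete. In the 75 genes with other tested probe sets, 56.6% of 129 others were called in the same direction; they all did so in 40 genes and none did in 21, and 10 genes had an opposite call. Among genes with calls under 4-fold, 18.8% of 1985 others did, but smaller differences are also called less often. The 56.6% lies between the limits set for the sequence explanation, at most 25% for it and at least 75% against it, so it stays open without the probe sequences. Loss of signal in AKR/J on probes drawn from another strain may be part of it. Of the 4-fold calls 62.3% were higher in C57Bl/6J, against 50.5% of the calls under 2-fold (two-sided Fisher exact p = 0.00157). That test counts probe sets of the same gene as independent, so its p is too small. By gene, 64 of the 111 calls of at least 4-fold were higher in C57Bl/6J, against 1033 of all 1991 called genes, which was not tested. A strain difference in expression remains open and was not tested separately.

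In the cell cycle list 14 of 26 genes were higher in AKR/J, with a median of 0.82, but the list's shift did not pass with an estimated correlation (adjusted p = 0.33) or by exact permutation of list means (adjusted p = 0.0751). The cell cycle median exceeded the endothelial one by 0.552 (95% bootstrap interval over genes 0.228 to 0.948). That interval resamples genes, which are not independent, and leaves out the spread between pools. It therefore cannot decide whether more endothelial cells alone would give the cell cycle difference. Sequence differences under the probes are argued against for the 8 of 14 called genes with another tested probe set, since 100% of 10 others had the same sign and 5 of them were called; the 6 remaining genes were not tested for this. The difference was present in both sets of the split, with medians of 0.588 in arrays 1, 2, 5, 6 and 1.16 in arrays 3, 4, 7, 8. Of 26 genes, 24 and 23 were above 0. Each set holds the strains in equal number, so the split could not by itself give a strain difference, and these medians add no separate support. Of 35 splits of the arrays, 1, the real one, gave a median over the 26 genes as large (highest other 0.697). This is the smallest share the splits allow, so they do not exclude chance. For the 14 called genes a strain difference in proliferation remains a candidate explanation, untested, as is the dividing cell type.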

How the results depend on the processing

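No paired analysis was possible because the replicate numbers of the strains do not overlap, and the planned block on array batch was not run because no batch is given. The fits on sets of arrays and the exact test of lists were chosen after the data were seen. Of 80 called named genes, 57 kept their call under every alternative with all 8 arrays that measured them, except the acinar covariate. Of these, 56 also did with each array left out, and between 5 and 10 called named genes were lost per array left out. Of 85 named genes, detection on all 8 arrays measured 67 and probe sets without the _x_at and _s_at suffixes 80. Genes missing there were not tested under that alternative. Leaving out single arrays gave 2047 to 2820 probe sets, 750 to 830 at least 2-fold, 1376 to 1859 genes, 7 to 10 lists and 0 to 1 hormone or Nnt genes, against 2968, 813, 1991, 8 and 1 (Ppy). The MAS5-type signals called 2259 probe sets, 1617 of them shared, and ended 16 named calls, those of Ucn3, Scg3, Ttr, Slc38a5, Clu, Jchain, Tek, Esam, Fabp4, Manf, Sel1l, Gstm1, Uqcrfs1, Tnfrsf1a, Fcgrt and Mgst1.

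The mean of all probe sets ended the calls of Ttr, Fabp4, Sel1l, Gsr and Sc5d (-0.26), and no filter those of Ppy, Slc38a5, Clu, Jchain, Cd52, Pfkp and Maf. H2-K1 went from -5.29 to -1.28 without C57Bl/6J array 8, because another probe set was then its brightest; the probe set used with all arrays gave -5.285. H2-D1 was -1.87 with the mean of its probe sets, and H2-Ab1 -1.29 and the acinar median -0.51 with the MAS5-type signals. With no filter, which adds members, the median of antigen presentation was -0.40 and that of the strain alleles 0.31. The endoplasmic reticulum stress list passed under 7 of the alternatives other than single arrays left out and the oxidative phosphorylation list was lost under 9, the estimated correlation and the acinar covariate included, and by the exact test.

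Detection on all 8 arrays left 499 probe sets at least 2-fold, with fewer tested. Hormone and Nnt calls were 2 with no filter (Ins2 and Iapp, not Ppy), 2 after a further quantile normalization (Ins2 and Ppy), 3 with trend and robust variance, and 0 in each set of 4 arrays. Arrays 1, 2, 5 and 6 alone gave 1054 probe sets, 64.0% higher in C57Bl/6J against 53.9%, and 904 genes; arrays 3, 4, 7 and 8 alone gave 403 probe sets, 366 at least 2-fold, and 403 genes, with fewer samples. With both sets as a block, 2481 genes passed. Camera with an estimated correlation and the exact test each passed 0 lists.

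The acinar covariate, correlated with strain at r = -0.987, left 4 probe sets, 4 at least 2-fold, 4 genes, 5 lists and 0 hormone or Nnt genes, because it removes nearly all of the strain contrast. Signs turned there for oxidative phosphorylation by camera (median 0.028), 6330403K07Rik (-0.11), Tmed11 (0.013), Ttr (-0.16), Tspan8 (0.0085), Cd52 (0.0893), Cdh5 (-0.41), Fabp4 (0.53), Cox6a1 (-0.14), Ifih1 (0.50), Oasl2 (1.46), Mgst1 (0.36) and Maf (0.35), with adjusted p of at least 0.738. Prdx2 turned to -1.64 with the mean of its probe sets, which disagree. The cause of the other changes was not tested.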

Other observations

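The gene groups and tests in this part were chosen after values were seen, except the test of neighbouring genes and the splits of the arrays for the counts of probe sets, genes and lists. Of 7 granin genes and relatives, 5 were higher in AKR/J, 1 was lower and 1 did not pass. Vgf, a granin-like neuropeptide precursor, was 5.87-fold higher in AKR/J (adjusted p = 0.000118) and Scg5, a chaperone of prohormone convertase, 2.18-fold (adjusted p = 5.41e-05), beside Chgb at 1.83-fold, while Chga was 1.21-fold lower (adjusted p = 0.0389) and Pcsk1n did not pass (adjusted p = 0.506). Of 8 genes linked to altered beta cell identity, Aldh1a3 and 4 others were higher in AKR/J, with Th, the rate-limiting enzyme of catecholamine synthesis, at 5.98-fold, Gucy2c at 4.68-fold, Dcx at 3.41-fold and Pappa2 at 3.39-fold. The neuropeptide gene Gal was lower in AKR/J, at a log2 value of 3.08 against 6.51 (adjusted p = 6.3e-07), and was detected on 2 of 4 AKR/J arrays, where its signal was near background, and Cck and Neurog3 did not pass (adjusted p = 0.0627 and 0.504).

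Of 6 measured genes of the regenerating family, Reg1 (2.10-fold), Reg2 (3.28-fold) and Reg3d (4.61-fold) were lower in AKR/J and 3 did not pass. Reg1 is also in the acinar list, which was lower on the same arrays (median -0.81). Genes of plasma proteins went both ways. Itih1 (at least 10.02-fold), F13a1 of coagulation factor XIII, which macrophages also express (6.75-fold), and Apoa2 (2.11-fold) were higher in AKR/J, and Hamp2 (at least 6.26-fold) and C8b (4.98-fold) were lower, while Apoh did not pass (adjusted p = 0.238). Of 10 pericyte genes, Higd1b (3.69-fold), Sparcl1 (3.68-fold), Ndufa4l2 (2.26-fold), Notch3 (1.97-fold) and Rgs5 (2.67-fold) were higher in AKR/J, and 5, among them Abcc9 and Kcnj8, did not pass.

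One hypothesis was that the AKR/J preparations held less acinar tissue. All acinar transcripts would then differ by 1 factor, provided that signals are proportional to transcript amount. The robust SD of the log2 difference over 25 members was 0.479, under the 0.5 above which this would be rejected, and the plain SD was 1.31, over the 0.5 required for support, so the values do not decide. Prss3 was 10.4-fold lower, with an SD of 1.37 on the log2 scale between AKR/J arrays. Ctrb1 was 1.25-fold lower, and Ctrc was higher. Ctrb1 and Cela3b (log2 differences -0.33 and -0.57) were bright, at 14.59 and 15.47 in AKR/J, where differences can be compressed. The dimmer Spink1 and Ptf1a (10.72 and 5.23) differed by -1.99 and -2.38. Unequal sizes among the lower genes therefore do not by themselves count against 1 factor. Compression was not tested, and Ctrc and Bhlha15 (0.32, not passed) were not lower. A lower acinar share and a strain difference in acinar genes may both be present.

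Called genes lay beside each other more often than shuffled calls did, with 400 neighbouring pairs both called against a mean of 350.7 and a highest of 409 in 10000 shuffles (one-sided permutation p = 9e-04). That strain differences come in chromosomal blocks is a candidate explanation, tested by these 400 pairs, as is co-expression of neighbours, and 59.8% of these pairs had the same direction.

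Of the 35 splits of the arrays into 4 and 4, 1, the real one, gave as many probe sets (2968, highest other 9). The same held for those at least 2-fold (813, highest other 7) and for genes (1991, highest other 6). A share of 1 in 35 is the smallest that these splits allow. The other splits mix the strains, which puts the strain difference into the spread within groups and lowers their counts. The splits therefore do not exclude chance for these counts. For the number of shifted lists, 7 splits gave at least 8 lists and the highest other gave 10. Apart from the real one, these splits kept most arrays of each strain together, so they held part of the strain contrast. Splits with the strains in equal number in each group gave at most 6 lists. Chance stays open there, since the splits cannot decide it.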
